A study of Mus musculus with 20 samples.

How the data were processed

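Cerebellar RNA of 20 male mice, 6 weeks old, had been hybridised to Affymetrix mouse exon arrays, which carry probe sets along the exons of each gene. Total RNA was extracted with TRIzol, treated with DNase I and cleaned on RNeasy columns before biotin labelling, per the labels' protocols. The mice fell into 4 groups of 5: Mecp2-null mice and wild-type littermates on the C57BL/6J strain, and mice carrying a MECP2 transgene and wild-type littermates on the FVB strain. Each mouse was treated as 1 biological replicate.

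The deposited table held 1 value for each of 1201338 probe sets on each of the 20 arrays, and all 20 columns were used. The values ran from 1.59 to 15.02 and were read as log2 signal as deposited, since that range is that of a log2 scale. The submitters' processing notes name GCOS version 1.1. The summary and normalization steps and the genome build are not given in the sources used here. Column medians lay between 5.63 and 5.68 and upper quartiles between 7.36 and 7.43, so the columns were used without further scaling. An array has no read depth, and the number of arrays limits the precision. Pairs of arrays of 1 group correlated at 0.9671 to 0.9817 over all probe sets. At most 1.23% of probe sets held equal values in such a pair, with a median of 1.01%, so no array was a copy of another.

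Probe sets were named through the platform annotation: 313617 had 1 gene symbol, 7413 had several and 880308 had none. Only those with 1 symbol entered the gene values. Of the 22359 symbols, 4021 were updated through the synonyms of a mouse gene table (assembly GRCm38.p6), 22061 matched that table and 298 kept the array's name. No coordinates are given, because the build of the array's annotation is not stated. Mecp2 itself was not analysed here, so the labels of genotype were not checked on the targeted gene. A gene's value was the median over its probe sets whose mean over the 20 arrays was above 5.617, the median of the table, with at least 3 such probe sets where the gene had 3 or more in all. This left 16963 genes, with a median of 11 probe sets in use, and 5396 genes were not tested.

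All 20 arrays entered 1 fit with 4 group means in limma 3.58.1 under R 4.3.3 (lmFit, then eBayes with a mean-variance trend). Moderated two-sided p-values were adjusted by Benjamini and Hochberg over the 16963 genes of each contrast, and a gene was called at an adjusted p under 0.05 with no minimum fold. The contrasts were null minus wild type within C57BL/6J, transgenic minus wild type within FVB, the difference of these effects (transgenic effect minus null effect), their mean, and wild-type FVB minus wild-type C57BL/6J. The comparisons share no control array. Every adjusted p of a gene below is from limma.

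The named genes were set by a rule: Mecp2, the 10 largest rises and 10 largest falls among the called genes of each genotype comparison, the 5 largest each way in the difference and mean contrasts, up to 4 called members of each gene list with the lowest p, and up to 10 genes called in both comparisons. A few further genes were chosen after their values were seen and are marked so. The 26 gene lists came from textbook knowledge. Their tests used camera with an inter-gene correlation preset to 0.01, adjusted over the lists of a contrast, with an estimated correlation, fry and an exact permutation test of a per-array score as alternatives. That score was the mean of the list minus the mean of all tested genes on the array. Of the lists, 25 had the minimum of 5 measured members, and the red blood cell list, with 4 of its 14 genes measured, was not tested. The lists, designs, naming rule and first set of alternatives were fixed before the data were examined.

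Gene spans came from the same gene table and were available for 16754 of the tested genes (98.8%), of which 2238 spanned over 100 kb. The long-gene score of an array was the mean log2 of those genes minus the mean of the other tested genes with a span. Groups were compared by an exact permutation test over the 252 splits of 10 arrays into groups of 5, whose smallest two-sided p is 0.00794.

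The procedure was tested on simulated data with the means and spreads of the real table, 16963 genes and 50 changed genes of each size per comparison. In the simulated null comparison 26% of changes of 0.3 log2 were recovered, 60% of those of 0.5, 94% of those of 0.8 and 100% of those of 1.2. In the simulated transgenic comparison the shares were 36%, 76%, 92% and 100%. Of the simulated calls, 0.709% in the null comparison and 6.75% in the transgenic comparison were unchanged genes. For the unchanged mean and strain contrasts, limma called 0 genes. The simulated strains thus did not differ, whereas the real ones did. Other splits of the real arrays called at most 1 gene in the null, 65 in the transgenic and 679 between strains (median 0 in each). Such splits can keep part of a real difference, so they do not give a false share. The simulated shares of unchanged genes may therefore be too low for the real arrays. Genes that move together were left out of the simulation, so its recovered shares may not hold there either.

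The alternatives were fits of each strain alone, the replicate number and the run of sample numbers as blocks, quantile normalization, arrays centred on their gene median, no filter on dim probe sets, only the genes above the median signal, the mean of the probe sets, eBayes without trend and with robust priors, array weights, other thresholds, other list tests, other definitions of a long gene, and each array left out in turn. A floor before the logarithm did not apply to values already on the log2 scale. The numbers opening the sample titles fell into 5 runs of close but not always consecutive numbers, each within 1 strain and holding both of its genotypes, and were treated as a possible batch. Alternatives added after the data were seen were the fit without 4 arrays, the gene median as a covariate, and the Purkinje list without Cck. The 4 arrays, picked for their gene medians, were wild-type C57BL/6J replicates 1 and 5, wild-type FVB replicate 2 and transgenic replicate 2. They are called below the 4 arrays that stood apart. Wild-type FVB replicate 4 was kept, though its gene median (8.04) was above that of wild-type C57BL/6J replicate 1 (8.035). The set is therefore not every array with an outlying median.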

Results

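Gene expression was measured with exon arrays in the cerebellum of 20 male mice aged 6 weeks, in groups of 5. Mice without Mecp2, the X-linked gene for a protein that binds methylated DNA, were set against wild-type littermates on the C57BL/6J strain, and mice with a MECP2 transgene against wild-type littermates on the FVB strain. The 2 comparisons ask what follows loss and gain of MeCP2, each within its own strain, and strain cannot be told apart from the kind of allele. Values of 16963 genes are given as log2 signal. Over these genes the first principal component, with 32.4% of the variance, separated the strains, and components 2 and 3 took 10.04% and 6.72%. Gene medians of the arrays ran from 7.84 in wild-type FVB replicate 2 to 8.075 in wild-type C57BL/6J replicate 5. Mecp2 was not analysed here.

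In the Mecp2-null cerebellum, Irak1, a kinase of interleukin-1 and Toll-like receptor signalling whose gene lies beside Mecp2, showed the largest rise. Its signal was 9.91 ± 0.115 against 8.91 ± 0.063 in wild type (SD, n = 5 each), a change of 1.001 ± 0.065 log2 (SE) or 2.001-fold (adjusted p = 7.58e-10). Smaller rises were those of the Slit receptor Robo2 by 0.41 ± 0.085 (adjusted p = 0.0355), the neuregulin receptor Erbb4 by 0.35 ± 0.055 (adjusted p = 0.00595), Aff2 by 0.40 ± 0.072 (adjusted p = 0.0187) and Auts2 by 0.32 ± 0.060 (adjusted p = 0.0187). The GABA-A receptor subunit genes Gabra2 and Gabra3 fell by 0.54 ± 0.101 and 0.51 ± 0.089 (adjusted p = 0.0200 and 0.0144). Among the other falls were Mdfi, an inhibitor of myogenic transcription factors, at -0.77 ± 0.110 (adjusted p = 0.00145), and Cnih2, an auxiliary protein of AMPA-type glutamate receptors, at -0.44 ± 0.056 (adjusted p = 0.000318).

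Of 16963 genes, 44 passed the threshold in the null, 10 higher and 34 lower, with a median absolute change of 0.41 log2. Unadjusted, 1566 genes had p under 0.05, against 848 by chance. The remaining rises were Stk33 (0.72, adjusted p = 0.0247), Wfikkn2 (0.60, 0.0372), Parp12 (0.44, 0.0481), Csrnp3 (0.40, 0.0414) and the TGF-beta co-receptor Tgfbr3 (0.28, 0.0481). The largest fall was that of Alpk2, at -0.85 ± 0.146 (adjusted p = 0.0144). It was followed, after Mdfi, by Pappa, a protease of IGF-binding proteins (-0.66, 0.0432), Slc13a1 (-0.60, 0.0247), Tmem159 (-0.54, 0.0481), Necab3 (-0.54, 0.0187), the neurexophilin Nxph4 (-0.51, 0.0344) and the formin Diaph2, Diap2 on the array (-0.47, 0.0144). Irak1, Erbb4 and Cnih2 stayed past the threshold in all 35 other settings tried, and Mdfi in 33 of 35. The other named genes did in fewer, from Diaph2 (31 of 35), Gabra3 (30 of 34), Aff2 (30 of 35) and Gabra2 (28 of 35) down to Robo2 (20 of 34), Ccnd1 and Gfap (16 and 15 of 35), Parp12 (13 of 34), Tgfbr3 (12 of 35) and Tmem159 (9 of 34). Here and below, the settings counted for a gene include a looser threshold of 0.1, which no called gene can fail. They also include fits without an array of the other strain, which leave the log2 change as it was. The count rested on few arrays. It was 28, 24, 23, 15 and 14 without null replicates 1 to 5, 5, 21, 25 and 5 without wild-type C57BL/6J replicates 1, 2, 4 and 5, and 29 without transgenic replicate 5. Wild-type replicates 1 and 5 had the highest gene medians of their strain (8.035 and 8.075), and without these and the 2 FVB arrays left out with them the count was 3. With each array centred on its gene median the split was 25 higher and 26 lower. Within the 3 runs of sample numbers holding this strain, 1 of which had only 1 array of each genotype, Irak1 differed by 0.92, 0.90 and 1.14 log2.

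By camera with the preset correlation, inhibitory synapse genes fell as a group in the null cerebellum. Of 24 measured GABA and glycine synapse genes, 18 were lower, 2 past the threshold over all genes (Gabra2 and Gabra3) and 6 adjusted over the list alone, with a median of -0.13 log2 (camera adjusted p = 0.00128). The call was lost with an estimated correlation (adjusted p = 0.379) and with fry (adjusted p = 0.0721). Imprinted genes, which are expressed from 1 parental copy, rose: 27 of 42 were higher, 0 past the threshold in limma over all genes and 4 adjusted over the list alone (camera adjusted p = 0.00128, and adjusted p = 0.0491 with an estimated correlation). Markers of neighbouring brain regions rose by a median of 0.09 (23 measured, adjusted p = 0.00128, and adjusted p = 0.174 with an estimated correlation) and those of meninges and choroid plexus by 0.05 (24 measured, adjusted p = 0.01002, and adjusted p = 0.872 with an estimated correlation). Heat shock and unfolded protein response genes fell by 0.10 (27 measured, 3 lower adjusted over the list alone, adjusted p = 0.0145, and adjusted p = 0.861 with an estimated correlation). In limma 0 members of these last 3 lists passed the threshold over all genes.

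Relative to all genes on an array, the GABA and glycine list shifted by -0.0682 ± 0.0215 (SE, exact permutation p = 0.0238), the imprinted list by 0.0771 ± 0.0183 (exact p = 0.00794), the neighbouring-region list by 0.116 ± 0.0483 (exact p = 0.0159), the meningeal list by 0.136 ± 0.176 (exact p = 0.635) and the heat shock list by -0.0667 ± 0.0269 (exact p = 0.0476). Of the 25 lists 5 had an exact p under 0.05, and 0 did after adjustment (lowest adjusted p = 0.198), against 5 by camera and 1 with an estimated correlation. Over 25 lists, 1 list alone at the smallest possible exact p of 0.00794 cannot pass after adjustment. The adjusted exact test therefore cannot decide on the imprinted list. The heat shock call was lost without null replicate 1 (adjusted p = 0.0698) and wild-type replicates 1 (0.0673) and 3 (0.0949). The meningeal call was lost without null replicate 2 (0.0912) and wild-type replicate 3 (0.450) and with centred arrays (0.0713). Without the 4 arrays that stood apart the neighbouring-region (0.516) and heat shock (0.101) calls were lost, and with the gene median as a covariate the neighbouring-region (0.200), heat shock (0.116) and meningeal (0.0506) calls. Within the runs of sample numbers the GABA and glycine list shifted by -0.103, -0.108 and -0.0141, and the imprinted list by 0.0364, 0.110 and 0.101.

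The other 20 lists did not pass in the null. Genes tied to MeCP2 by earlier work (27 measured, camera adjusted p = 0.247) held Irak1, with 4 higher and 4 lower adjusted over the list alone. Genes beside Mecp2 on the X chromosome (33 measured, 0.324) held Irak1, with 1 higher and 2 lower adjusted over the list alone. Bergmann glia and astrocyte markers (24 measured, 0.149) held Gfap, the astrocyte filament gene, which fell by 0.42 (adjusted p = 0.0427), with 0 higher and 2 lower adjusted over the list alone. In the remaining 17 lists limma called 0 members over all genes. Their camera adjusted p was 0.9996 for MeCP2 co-factors and DNA methylation genes, granule cells, interneurons and unipolar brush cells, ribosomal proteins, voltage-gated channels, and neurotrophin, CREB and IGF signalling, 0.886 for glutamate receptors and for glucocorticoid-responsive genes, and 0.699 for oligodendrocytes and myelin. It was 0.647 for immediate early genes, 0.303 for oligodendrocyte precursors, 0.296 for endothelium and mural cells and for cholesterol synthesis, 0.247 for Purkinje cells and for microglia, 0.138 for oxidative phosphorylation and 0.0518 for interferon-response genes. Adjusted over the list alone, 2 glucocorticoid-responsive genes were lower, 1 Purkinje marker was higher and 2 were lower, and 1 gene each was lower among interneuron markers, cholesterol synthesis, glutamate receptors and interferon-response genes. Interferon-response genes passed in several other settings, including without null replicates 1 (0.0225) and 5 (0.0211), wild-type C57BL/6J replicates 3 (0.00247) and 5 (0.0109), transgenic replicate 1 (0.0483) and wild-type FVB replicates 1 (0.0424) and 5 (0.0370). Astrocyte markers passed without null replicate 1 (0.0298) and oxidative phosphorylation without wild-type replicate 4 (0.0360). The median of all genes was -0.036 in the null, and camera compares a list with all genes, so a list with a negative median could have the direction higher. The immediate early genes did (median -0.06, mean shift of 0.0111 relative to all genes on an array), though they did not pass.

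In the transgenic cerebellum, the neuropeptide gene Cck fell most, by 1.25 ± 0.074 log2 (adjusted p = 8.59e-11). Its signal was 8.98 ± 0.209 against 10.2 ± 0.078 in wild type (SD, n = 5 each), a fold of 0.422. Other large falls were those of the calcium/calmodulin-dependent kinase Camk1d by 0.63 ± 0.078 (adjusted p = 5.94e-05), the potassium channel partner Kcnip4 by 0.62 ± 0.108 (adjusted p = 0.00273), the netrin family gene Ntng1 by 0.64 ± 0.113 (adjusted p = 0.00285) and the glycogen phosphorylase Pygm by 0.70 ± 0.062 (adjusted p = 2.24e-07). Gabra3, which fell in the null, rose by 0.72 ± 0.089 (adjusted p = 5.94e-05). The growth factor genes Tgfb1 and Gdf11 rose by 0.63 ± 0.098 and 0.63 ± 0.105 (adjusted p = 0.000886 and 0.00184), and Gchfr, a regulator of tetrahydrobiopterin synthesis, by 0.76 ± 0.102 (adjusted p = 0.00016).

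Of the 16963 genes, 200 passed, 95 higher and 105 lower, with a median absolute change of 0.37 log2 (1812 with unadjusted p under 0.05, 848 by chance). The other largest rises were the spexin gene Spx, B230216G23Rik on the array (0.76, adjusted p = 0.00253), D630039A03Rik (0.74, 0.0235), Zcchc12 (0.74, 0.0202), the prohormone convertase Pcsk1 (0.64, 0.0202), Magee2 (0.63, 0.0238) and Olfr666 (0.62, 0.0457), the last 2 resting on 1 probe set each. The other largest falls were 6530403H02Rik (-0.90, 0.000352), Prr16 (-0.76, 3.03e-06), Pcolce2 (-0.62, 0.0215), Slc16a6 of the monocarboxylate transporter family (-0.61, 0.000587) and 2810482M11Rik (-0.61, 0.0178, 1 probe set). Gdf11 probe sets disagreed, since with their mean in place of their median Gdf11 also changed in the null (-0.70, adjusted p = 2.30e-06). The count was 126 without transgenic replicate 1, 132 without wild-type FVB replicate 2 and 118 without replicate 3, and 86 with the 10 FVB arrays fitted alone. Cck, Pygm, Camk1d, Kcnip4, Ntng1, Gabra3, Tgfb1, Gdf11 and Gchfr stayed past the threshold in every other setting that tested them (34 or 35), whereas Olfr666 did in 11 of 34, Robo2 and Kdr in 9 of 34, Meg3 in 18 of 35 and Gad2 and Cacnb4 in 22 of 35. With the run of sample numbers as a block 200 genes were called, 75 higher and 125 lower. Within the runs of this strain, the first of which had 1 transgenic array, Cck differed by -1.54 and -1.17 log2.

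By camera with the preset correlation, markers of cell types moved apart in the transgenic cerebellum. Microglia and macrophage markers rose: 21 of 24 were higher, with a median of 0.17 log2 (camera adjusted p = 2.64e-05, and adjusted p = 0.160 with an estimated correlation), and the complement gene C1qb rose by 0.61 ± 0.138 (adjusted p = 0.0238). Adjusted over the list alone 2 were higher. Purkinje cell markers fell by a median of 0.07 (16 of 22 lower, adjusted p = 0.00307, and adjusted p = 0.414 with an estimated correlation), with Cck the 1 member past the threshold over all genes and adjusted over the list alone. Cck carried much of that shift: without it, an alternative chosen after its values were seen, camera did not call the list (adjusted p = 0.0642). Granule cell markers fell by 0.07 (18 of 23 lower, adjusted p = 0.00181, and adjusted p = 0.160 with an estimated correlation), with the synaptic gene Rims3 at -0.22 (adjusted p = 0.0177), the 1 member past the threshold either way of adjusting, including adjusted over the list alone. Oligodendrocyte precursor markers rose by 0.13 (14 measured, 0 past the threshold in limma over all genes, 2 higher adjusted over the list alone, adjusted p = 0.0262, and adjusted p = 0.414 with an estimated correlation).

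Imprinted genes fell in the transgenic (42 measured, 1 higher and 5 lower, and 1 and 7 adjusted over the list alone, adjusted p = 0.0262, and adjusted p = 0.160 with an estimated correlation). Among them were Nap1l5 (-0.33, adjusted p = 0.00907), Plagl1 (-0.40, 0.0177), the noncoding RNA genes Mirg (-0.41, 0.0210) and Meg3 (-0.24, 0.0411), and Peg3 (-0.33, 0.0317). Glucocorticoid-responsive genes fell (23 measured, 3 lower adjusted over the list alone, adjusted p = 0.00398, and adjusted p = 0.414 with an estimated correlation), with the metallothionein gene Mt2 at -0.41 (adjusted p = 0.0152) past the threshold over all genes. Of 40 voltage-gated channel genes, 1 was higher (Kcnc4, named after its value was seen, 0.31, adjusted p = 0.0418) and 4 were lower, among them Kcnh7 (-0.56, 0.0152), the sodium channel Scn1a (-0.30, 0.0212) and the calcium channel subunit Cacnb4 (-0.22, 0.0374), and 4 and 12 passed adjusted over the list alone. Camera did not call that list (adjusted p = 0.0869), and the exact test did (shift -0.0493 ± 0.0120, exact adjusted p = 0.0496).

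Relative to all genes on an array, the microglia list shifted by 0.159 ± 0.0309 (SE), the Purkinje list by -0.125 ± 0.0280 and the granule list by -0.0721 ± 0.0142, each with an exact permutation p of 0.00794 and an exact adjusted p of 0.0496. Without Cck the Purkinje list shifted by -0.0708 ± 0.0265, with the same exact values. The exact test passed after adjustment only because 4 lists (microglia, Purkinje, granule and voltage-gated channel genes) tied at the smallest possible exact p. The precursor list shifted by 0.104 ± 0.0305 (exact adjusted p = 0.0794), the imprinted list by -0.0493 ± 0.0202 (0.165) and the glucocorticoid list by -0.127 ± 0.0646 (0.298). Camera called 6 lists, or 10 without wild-type FVB replicate 4, and 0 with an estimated correlation, where 3 had an unadjusted p under 0.05. The imprinted call was lost without transgenic replicates 1 (adjusted p = 0.0624) and 3 (0.0548) and wild-type replicates 2 (0.111) and 5 (0.0521), the precursor call without transgenic replicate 1 (0.0624) and wild-type replicates 3 (0.0701) and 5 (0.0521), and the glucocorticoid call without transgenic replicate 4 (0.0673). With the run of sample numbers as a block the imprinted and precursor calls were lost (both 0.0832), and with the gene median as a covariate the imprinted call (0.0585). Within the runs the microglia list shifted by 0.116 and 0.164, the Purkinje list by -0.175 and -0.120 and the granule list by -0.0889 and -0.0601.

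The other 18 lists did not pass camera in the transgenic. Genes tied to MeCP2 (adjusted p = 0.460) held Gad2, which makes GABA (0.24, 0.0300), the splicing factor Rbfox1, A2bp1 on the array (-0.38, 0.000352), and Meg3, with 2 higher and 3 lower adjusted over the list alone. Genes beside Mecp2 (0.287) held the plexin Plxna3 (0.30, adjusted p = 0.0243; 2 higher and 1 lower adjusted over the list alone). GABA and glycine synapse genes (0.149) held Gabra3 and Gad2 (3 higher adjusted over the list alone), and interneuron and unipolar brush cell markers (0.117) Gad2 (2 higher adjusted over the list alone). Endothelial and mural markers (0.0712) held the pericyte marker Rgs5 (0.33, 0.00652) and the VEGF receptor Kdr (0.42, 0.0481), with 3 higher adjusted over the list alone. Glutamate receptor and postsynaptic genes (0.714) held the scaffold Dlg1 (-0.30, 0.00184; 1 higher and 2 lower adjusted over the list alone). In the other 12 lists limma called 0 members over all genes. Their camera adjusted p was 0.902 for MeCP2 co-factors, oligodendrocytes and heat shock genes, 0.867 for meninges and for neurotrophin, CREB and IGF signalling, 0.984 for ribosomal proteins, 0.736 for astrocytes (3 higher and 2 lower adjusted over the list alone) and 0.429 for interferon-response genes. It was 0.287 for neighbouring regions, 0.138 for immediate early genes, 0.0712 for cholesterol synthesis and 0.0651 for oxidative phosphorylation. Adjusted over the list alone, 1 neighbouring-region gene was lower and 1 interferon-response gene was higher. Oxidative phosphorylation passed without transgenic replicates 3 (0.00709), 4 (0.0107) and 5 (0.0243) and wild-type replicates 4 (0.00171) and 5 (0.0383), and cholesterol synthesis without transgenic replicates 2 (0.00448) and 5 (0.0352) and wild-type replicate 1 (0.0363). Endothelial markers passed without transgenic replicate 2 (0.0310) and wild-type replicates 1 (0.0236) and 4 (0.0476), and immediate early genes without transgenic replicate 2 (0.0310) and wild-type replicate 4 (0.0142). Interneuron markers passed without wild-type replicate 4 (0.0192) and channel genes without wild-type replicate 1 (0.0478).

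**Figure D1:**
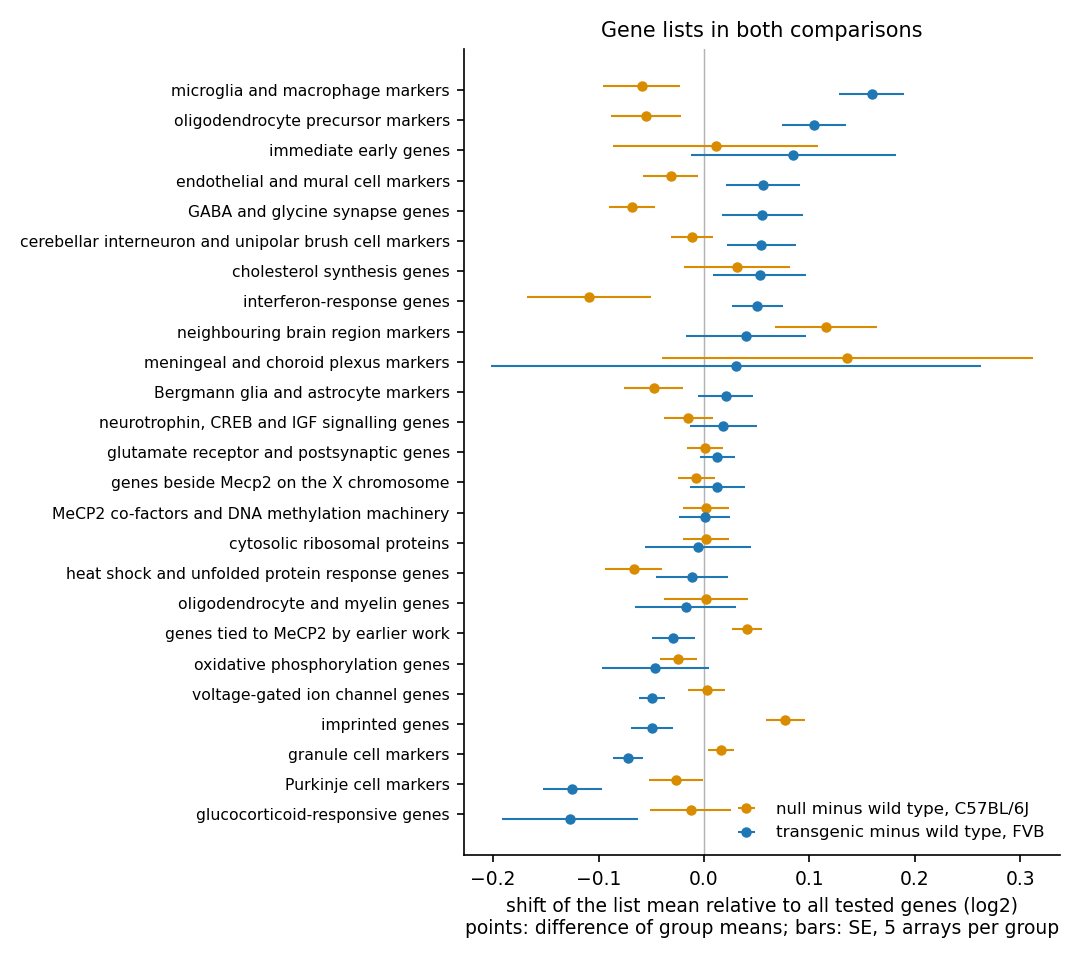
Each point is the difference of group means of a gene list's score (mean log2 of the list minus the mean of all tested genes on the array) with its SE, over 5 arrays per group, for the null (orange) and the transgenic (blue). Microglia and macrophage markers shifted by 0.159 in the transgenic, and Purkinje cell markers by -0.125, or by -0.0708 without Cck.

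In total 10 genes were called in both comparisons, and each of them changed in opposite directions with loss and gain of MeCP2. Lower in the null and higher in the transgenic were Gabra3 (-0.51 and 0.72), Mdfi (-0.77 and 0.59), Nxph4 (-0.51 and 0.57), Necab3 (-0.54 and 0.52), Tmem64 (-0.35 and 0.45), the secretory-pathway kinase Fam20c (-0.39 and 0.42), the cyclin Ccnd1 (-0.35 and 0.39) and Cnih2 (-0.44 and 0.36). Higher in the null and lower in the transgenic were Robo2 (0.41 and -0.34) and Erbb4 (0.35 and -0.30). Independent lists would share 0.190 genes of the first kind and 0.0619 of the second (one-sided Fisher's exact p = 1.15e-11 and 0.00165). These p-values are descriptive, since genes are not independent replicates and both comparisons share 1 estimate of each gene's spread. The count was 5 and 4 without null replicates 4 and 5, 3, 6 and 3 without wild-type C57BL/6J replicates 1, 4 and 5, and 16 without wild-type FVB replicate 4. Without the 4 arrays that stood apart it was 2, with 3 genes called in the null. In several settings 1 gene was called in both with the same sign: Stap2, lower in both, beside 9 opposite genes with the run of sample numbers as a block (-0.33 and -0.27, adjusted p = 0.0141 and 0.0239) and beside 9 without wild-type FVB replicate 2, and Pappa, lower in both, beside 7 without null replicate 2.

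**Figure D2:**
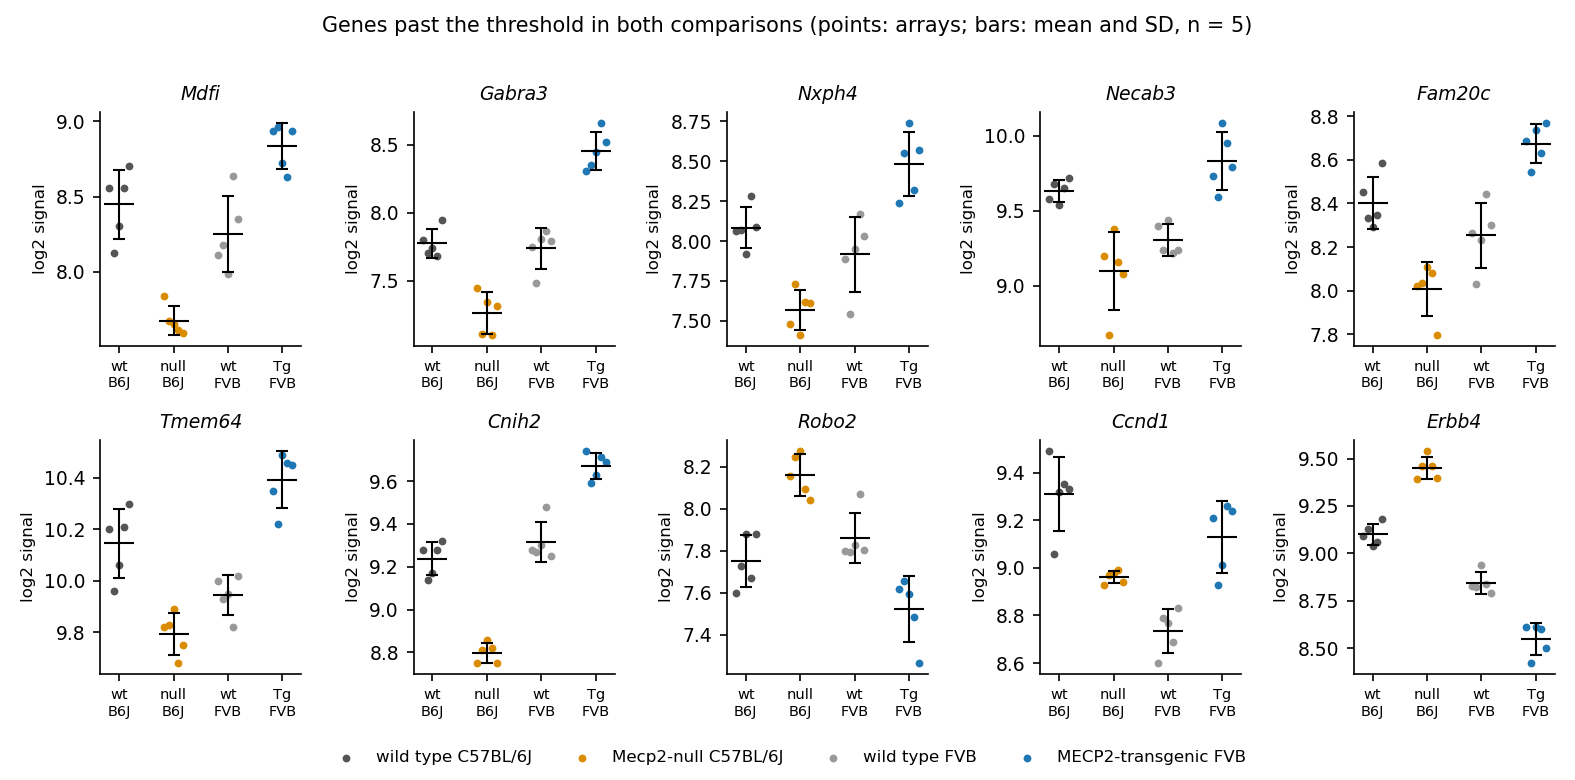
Log2 signal of the 10 genes past the threshold in both comparisons, with 1 point per array and bars for mean and SD (n = 5 per group). Within its strain, Gabra3 was lower by 0.51 in the null and higher by 0.72 in the transgenic, and Robo2 and Erbb4 went the other way.

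Most genes called in 1 comparison also had the opposite sign in the other. Of the 200 genes called in the transgenic, 170 (85%) had the opposite sign in the null, 86 of the 95 higher and 84 of the 105 lower, with a median ratio of null to transgenic effect of -0.351. The share was 77.5% with the run of sample numbers as a block and 76.6% without null replicate 2. Of the 44 genes called in the null, 34 (77.3%) had the opposite sign in the transgenic. The difference of the effects passed for 291 genes, 194 above and 97 below 0 (177 and 196 with centred arrays). The largest differences upward were Alpk2 (1.39, adjusted p = 0.000393), Mdfi (1.36), Gabra3 (1.23), Pcsk1 (1.14) and Spx (1.11), and downward Cck (-1.22, adjusted p = 2.75e-07), Pcolce2 (-1.08), 2810482M11Rik (-0.996), Ntng1 (-0.97) and 6530403H02Rik (-0.94). Irak1 differed by -0.90 (adjusted p = 2.39e-06), with a change of 0.10 in the transgenic (adjusted p = 0.641). Camera called 5 lists for the difference: microglia (adjusted p = 0.000332, and adjusted p = 0.169 with an estimated correlation), GABA and glycine synapse genes (0.00390, and 0.424 with an estimated correlation) and oligodendrocyte precursors (0.0389, and 0.424 with an estimated correlation) lay higher. Imprinted genes (0.000343, and 0.0212 with an estimated correlation) and granule cell markers (0.0389, and 0.424 with an estimated correlation) lay lower. The granule and precursor calls were kept in 16 and 19 of 34 other settings. The granule call was lost without null replicates 1 (adjusted p = 0.0504), 3 (0.0597) and 4 (0.0698), wild-type C57BL/6J replicate 2 (0.0544), transgenic replicates 2 (0.0600) and 5 (0.0556) and wild-type FVB replicates 2 (0.0649) and 4 (0.0830). The precursor call was lost without null replicates 1 (0.0710) and 4 (0.0618), wild-type C57BL/6J replicate 5 (0.0610), transgenic replicates 1 (0.0649), 2 (0.0600) and 3 (0.0563) and wild-type FVB replicate 3 (0.0692). With the run of sample numbers as a block both were lost (0.0598 for granule cells and 0.0757 for precursors), as they were without the 4 arrays that stood apart (0.109 and 0.112) and with the gene median as a covariate (0.0525 and 0.0704).

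Over all 16963 genes the opposition was weak. The effects correlated across genes at r = -0.128 (Spearman's rho = -0.0955), and 52.1% of genes had opposite signs. Genes are not independent replicates. Over all genes r was -0.0799 without null replicate 2, -0.0825 without transgenic replicate 4, -0.209 without transgenic replicate 2, and -0.0788 with the run of sample numbers as a block. No run held both strains, so no correlation could be computed within one.

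**Figure D3:**
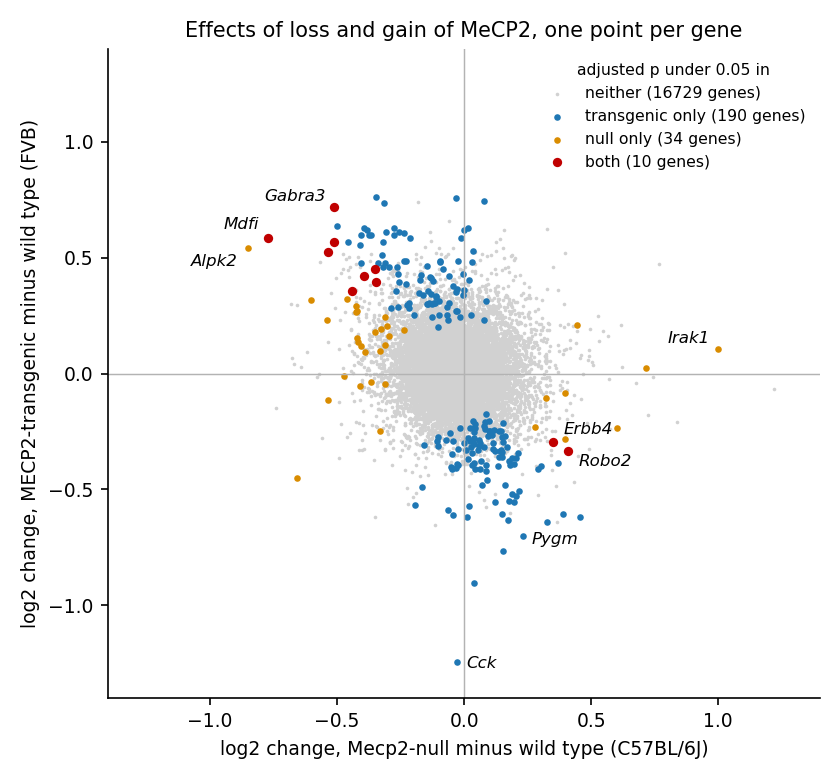
Each point is 1 of 16963 genes, with its log2 change in the null on the x axis and in the transgenic on the y axis, coloured by the comparison in which its adjusted p was under 0.05. The 10 genes called in both lie in the upper left and lower right, while Irak1 (1.001 and 0.10) and Cck (-0.03 and -1.25) moved along one axis.

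The mean of the 2 effects, which a gene can pass through 1 genotype alone, passed for 9 genes, 2 higher and 7 lower (6 and 8 with centred arrays), with 1286 genes at an unadjusted p under 0.05. It was higher for Irak1 (0.55, adjusted p = 8.39e-08) and the neurturin receptor gene Gfra2 (0.29, 0.0492). It was lowest for Cck (-0.64, 8.39e-08), Pappa (-0.56, 0.0321), Prr16 (-0.31, 0.0327), the neurotensin receptor gene Ntsr2 (-0.30, 0.0456) and Stap2 (-0.29, 0.0045). Of these 7 genes, Pappa, Ntsr2 and Stap2 lay lower in both genotypes, at -0.66 and -0.45, -0.29 and -0.30, and -0.33 and -0.25 (null and transgenic). The others moved mainly in 1 genotype, and the difference of effects passed for each: Irak1 changed by 1.001 and 0.10, Gfra2 by -0.01 and 0.58, Cck by -0.03 and -1.25 and Prr16 by 0.15 and -0.76. The count was 4 without null replicates 1 or 4, wild-type C57BL/6J replicates 1 or 5, transgenic replicate 4 or wild-type FVB replicate 3, and 5 without wild-type FVB replicate 1. Camera called 8 lists for the mean, all of them lost with an estimated correlation. Purkinje cells (adjusted p = 0.000673, and adjusted p = 0.548 with an estimated correlation), oxidative phosphorylation (0.00609, and 0.848 with an estimated correlation), glucocorticoid-responsive genes (0.0121, and 0.660 with an estimated correlation) and granule cells (0.0174, and 0.548 with an estimated correlation) were lower. Neighbouring regions (0.000924, and 0.386 with an estimated correlation), microglia (0.0174, and 0.552 with an estimated correlation), cholesterol synthesis (0.0174, and 0.848 with an estimated correlation) and meninges (0.0374, and 0.848 with an estimated correlation) were higher. The microglia list went opposite ways, with a mean of -0.0937 log2 in the null and 0.171 in the transgenic, and its mean was set by the transgenic. Without Cck the Purkinje list kept an adjusted p of 0.0119. With an estimated correlation camera called 0 lists, 1 having an unadjusted p under 0.05, and fry also 0.

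Long genes were lower in the transgenic cerebellum. Of the 103 genes called lower with a known span, 60 (58.3%) spanned over 100 kb, against 13.4% of tested genes (odds ratio 9.27, Fisher's exact p = 9.39e-27), among them Prr16, Camk1d, Ntng1, Kcnip4, Rbfox1, Dlg1 and Scn1a. Of the 95 called higher, 14 (14.7%) did (exact p = 0.651). In the null 7 of the 10 genes called higher were long (odds ratio 15.2, exact p = 6.23e-05), among them Robo2, Erbb4, Auts2 and Aff2, and 7 of the 33 called lower (21.2%, exact p = 0.196). Genes are not independent replicates in these tests. Per array, long genes exceeded shorter genes by 0.244 ± 0.00828 log2 in the transgenic and 0.279 ± 0.00749 in wild-type FVB (SD, n = 5 each). The difference of -0.0349 ± 0.00499 (SE) gave an exact permutation p of 0.00794, the smallest the design allows. In the null the score was 0.306 ± 0.0340 against 0.279 ± 0.0119, a difference of 0.0272 ± 0.0161 that did not pass (exact p = 0.0873). Without null replicate 3 it was 0.0348 (exact p = 0.00794), and without null replicate 2, which lay highest at 0.364, it was 0.0127 (exact p = 0.206). Of the other definitions of a long gene it passed over 200 kb (0.0342, exact p = 0.0397) and among genes matched on expression (0.0306, exact p = 0.0238), but not over 50 kb (0.0142, exact p = 0.429). The effects differed between the genotypes by -0.0621 (exact p = 0.000346 over 63504 joint splits). Within the runs of sample numbers the transgenic difference was -0.0444 and -0.0334, and the null difference 0.00742, 0.00126 and 0.0599.

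**Figure D4:**
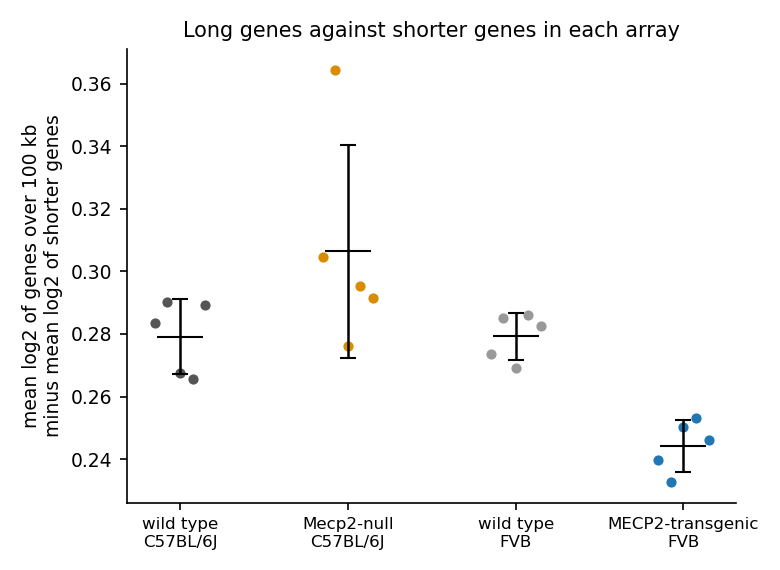
For each array, the mean log2 signal of 2238 genes over 100 kb minus that of the other tested genes with a known span, with bars for mean and SD (n = 5 per group). The 5 transgenic arrays lie between 0.233 and 0.253, all below the 5 wild-type FVB arrays, and null replicate 2 lies apart at 0.364.

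Across length groups the median change in the transgenic went from 0.02 log2 for genes up to 10 kb through 0.01 at 10 to 30 kb, 0.00 at 30 to 100 kb and -0.01 at 100 to 300 kb to -0.03 over 300 kb. In the null it went from -0.04 for genes up to 10 kb to 0.01 over 300 kb. Over 300 kb, 31 genes were called lower and 4 higher in the transgenic, and up to 10 kb 10 were lower and 23 higher.

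The wild types of the strains differed far more than the genotypes. In FVB 455 genes were higher and 1543 lower than in C57BL/6J (957 and 1067 with centred arrays, 563 and 1383 after quantile normalization), 93 of them by over 1 log2. Among genes named above, the strains differed for Parp12 (-1.26, adjusted p = 7.77e-10), Alpk2 (-1.44, 9.06e-08), Gabra2 (0.91, 4.09e-07), C1qb (-0.83, 0.000133), Gfap (-0.59, 5.16e-05) and Ccnd1 (-0.57, 4.65e-06). Strain cannot be told apart from the batch of animals or arrays in this contrast. These are differences of array signal, and sequence variants under probes, weighed below for Irak1 alone, were not tested for them.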

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

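The tests of a smaller share of neurons, of repression by MeCP2 in trans, of a changed segment around the targeted locus, of the 4 arrays left out and of the gene median as a covariate were chosen only after the results were seen.

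The first pattern weighed is the opposite effect of loss and gain of MeCP2. If the level of signal across the array were the cause, adjusting for the gene median should weaken the correlation across genes. It went instead from r = -0.128 to -0.162, and to -0.166 without the 4 arrays, a set that left in wild-type FVB replicate 4. Over the arrays left out in turn r had an SD of 0.0313, which is not its sampling spread, since those fits share most arrays. Other splits of the arrays gave r from -0.257 to 0.202, so nothing is drawn from the size of these shifts. Neither step weakened the correlation. Without those 4 arrays only 3 genes were called in the null and 2, both of opposite sign, in both comparisons, so the part they play in the overlap of 10 genes stays open. Of 100 splits of the arrays within strains, 1, the real one, gave 10 genes called in both comparisons with opposite signs (highest other 0). In each other split at least 1 comparison had no called gene in limma, so that count says nothing about direction. Of 100 splits of the C57BL/6J arrays, 4, the real one included, gave as many of the transgenic genes on one side (170, highest other 180), and 3 gave more. Chance is therefore less likely for that share but was not excluded, since the tests by splits were not corrected for their number. For r, 7 of the 100 splits within both strains gave a value of such size (0.128, highest other 0.257), so chance was not excluded for the correlation over all genes. The gain against the loss of MeCP2 and the strain, which is confounded with it, both stay open and were not tested apart.

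The second pattern weighed is the lower signal of long genes in the transgenic. The gene median as a covariate left the shift at -0.0354 (exact p = 0.00794), so the level of signal does not account for it. A smaller share of neurons, taken to raise markers of every other cell type alike, stays open. Microglia markers, the highest of 5 such lists, rose over oligodendrocyte markers, the lowest, by 0.176 ± 0.0599 (exact p = 0.0159, not corrected for that choice). A change in microglia themselves would give the same gap, so it cannot decide. Purkinje and granule cell markers fell, as given above. Microglia, precursor, endothelial and astrocyte markers shifted by 0.159, 0.104, 0.0560 and 0.0207, and oligodendrocyte markers by -0.0174. Transcript size on the array stays open: genes of 100 kb or less with many probe sets shifted by -0.00965 ± 0.00716 (exact p = 0.214), too imprecise to decide. The genotype itself stays open as a biological explanation that was not tested.

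The third pattern weighed is Irak1, which doubled in the null and showed no called change in the transgenic. A sequence variant under a few probes was argued against, because 80.8% of the 26 probe sets were higher by 0.5 log2 or more and all 26 were higher, with a median of 0.99. Repression of Irak1 by MeCP2 in trans was taken to need a change of -0.250 log2 or below in the transgenic. The 95% interval there, -0.0310 to 0.239, argues only against repression that deepens with added MeCP2 in FVB. Repression already complete at the wild-type level would give no further fall, so repression in trans stays open. A changed segment around the targeted locus, such as DNA kept from the cells in which the allele was made, remains a candidate explanation. Of 32 other genes beside Mecp2, 2, named after their values were seen, changed in the null when adjusted over the list alone, Irak1 included. They were Bcap31 (-0.27, adjusted p = 0.0149) and Plxnb3 (-0.22, adjusted p = 0.0384). The low p of Irak1 itself eased that adjustment for them, and the list was not adjusted without Irak1. The 2 genes therefore cannot decide for a segment. Bcap31 and Plxnb3 fell while Irak1 rose, and the effect of losing MeCP2 itself was not separated from that of the segment.

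The counts of called genes exceeded those of other splits in each contrast, where 1 of 100 splits, the real one, gave as many, the fewest possible. Chance was thus unlikely to give the counts of the null, transgenic and strain contrasts. For the difference and the mean both strains were split at once, which tests only for no effect in either genotype. Those splits do not bear on whether the effects differ or are shared. The real and the highest other counts were 44 and 1 in the null, 200 and 65 in the transgenic, 291 and 29 for the difference, 9 and 3 for the mean and 1998 and 679 between strains. For the numbers of lists called by camera chance was not excluded, since 20 of 100 splits gave at least the 5 lists of the null and 24 at least the 6 of the transgenic, with 10 the highest other in both. The other splits called a median of 2 lists in the null and 3 in the transgenic.

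The difference of the 2 effects passed for 291 genes, and the named genes among them were far apart between the genotypes (transgenic effect minus null effect, log2). It was positive for Alpk2 (1.39), Mdfi (1.36), Gabra3 (1.23), Pcsk1 (1.14), Spx (1.11), Nxph4 (1.08), Necab3 (1.06), Zcchc12 (1.05), Magee2 (1.02), C1qb (0.92), Slc13a1 (0.92), Tgfb1 (0.90), Fam20c (0.81), Cnih2 (0.80), Tmem64 (0.80), Gchfr (0.79), Tmem159 (0.77), Ccnd1 (0.74), Gfap (0.69), Gdf11 (0.62), Gfra2 (0.60), Diaph2 (0.46), Rgs5 (0.44), Plxna3 (0.43) and Gad2 (0.37). It was negative for Cck (-1.22), Pcolce2 (-1.08), 2810482M11Rik (-0.996), Ntng1 (-0.97), 6530403H02Rik (-0.94), Pygm (-0.93), Prr16 (-0.92), Irak1 (-0.90), Wfikkn2 (-0.83), Camk1d (-0.80), Kcnh7 (-0.75), Robo2 (-0.75), Plagl1 (-0.70), Mirg (-0.70), Csrnp3 (-0.68), Erbb4 (-0.65), Kcnip4 (-0.63), Slc16a6 (-0.57), Rbfox1 (-0.55), Tgfbr3 (-0.51), Aff2 (-0.48), Nap1l5 (-0.45), Auts2 (-0.43), Rims3 (-0.37), Meg3 (-0.36), Scn1a (-0.36) and Dlg1 (-0.34). The mean log2 over list members differed by 0.265 for microglia, 0.206 for oligodendrocyte precursors, 0.170 for GABA and glycine synapse genes, -0.0415 for granule cells and -0.0799 for imprinted genes, and the long-gene score by -0.0621. With an estimated correlation camera kept the imprinted list (adjusted p = 0.0212 with an estimated correlation) and lost microglia (adjusted p = 0.169) and the other 3 (adjusted p = 0.424 each).

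An array stood apart from the other 4 of its group in 21 of 364 groups of values tested (5.77%), where chance gives about 1 in 20 (18.2). The gap to the nearest array, as a share of the group's range, was above the critical value in transgenic replicate 2 for 6530403H02Rik (0.762), Gfap (0.780), Ntsr2 (0.729) and the gene median (0.714), in transgenic replicate 3 for Rims3 (0.741), in null replicate 2 for Cck (0.739) and Gad2 (0.786), in null replicate 3 for Peg3 (0.767) and in null replicate 5 for Fam20c (0.714), Stk33 (0.767) and the oxidative phosphorylation score (0.807). It was so in wild-type FVB replicate 4 for Cnih2 (0.783), Robo2 (0.873) and the Purkinje score (0.741), in FVB replicate 1 for Gabra2 (0.771) and in FVB replicate 3 for Nap1l5 (0.741). In wild-type C57BL/6J it was so in replicate 3 for Pcolce2 (0.805) and the oligodendrocyte (0.867) and meningeal (0.786) scores, in replicate 5 for Spx (0.855) and in replicate 1 for the MeCP2 co-factor score (0.746).

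Probe sets without a gene symbol, which entered no gene value, also differed. Of 358227 such probe sets above the filter, 107 passed in the null (48 higher and 59 lower) and 405 in the transgenic (76 higher and 329 lower), against at most 26 and 5 in 20 random splits of the same arrays.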

How the results depend on the processing

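The fit without the 4 arrays that stood apart, the gene median as a covariate and the Purkinje list without Cck were chosen only after the data were seen, as was the exact test of long genes within blocks. No called result of a named gene and no called list reversed under any setting, and of the 132 called results of named genes 102 to 125 were kept when 1 array was left out, 76 without the 4 arrays and 116 with the covariate. The named results were picked as called in these same arrays, and several settings leave the log2 change as it was. The lack of reversals among called results therefore says little about stability. The 1 reversal was of an uncalled result, Gdf11 in the null, at -0.70 with the mean of the probe sets against 0.01. The cause was not tested here or for the changes below, except where fewer arrays or genes or another threshold entered by construction. The signal over background limits dim genes, and Magee2 and Olfr666 rested on 1 probe set.

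With the strains fitted alone, with fewer arrays behind each estimate of the spread, 86 genes were called in the transgenic. Replicate numbers showed no clear pairing of the mice: same-numbered arrays correlated in their deviations at -0.106 to 0.146. Those values were not set against differently numbered arrays, so a pairing was not excluded. With the replicate block 31, 170, 257 and 7 genes were called in the null, the transgenic, their difference and their mean, and 3 lists for the difference. Arrays of the same run of sample numbers correlated at 0.0193 and 0.0143, others at -0.0108 and -0.0181 (null, transgenic). With the run as a block r was -0.0788 and 3 lists were called for the difference, as after quantile normalization. The long-gene shift was 0.0272 in the null (exact p = 0.0833) and -0.0365 in the transgenic (exact p = 0.00952) when arrays were permuted within runs. With centred arrays 14 genes were called for the mean and 17 in both comparisons. Without the filter 20 genes were called in the null and 3 for the mean, and r was -0.0830. With only the genes above the median signal r was -0.216, the null long-gene shift 0.0430 (exact p = 0.0159), and camera called 0 lists in the transgenic (8 with an unadjusted p under 0.05) and 1 for the difference. There only 23 lists had enough members, and microglia and neighbouring regions were not tested. With the mean of the probe sets 130, 503, 704, 19 and 3106 genes were called in the null, transgenic, difference, mean and strain contrasts, 50 in both comparisons, and r was -0.185. Without trend 19 genes were called in the null, 5 for the mean and 5 in both. With array weights 89 were called in the null and 17 in both, r was -0.174, and 10 lists were called in the transgenic and 3 for the difference. At an adjusted p under 0.1 the counts were 78, 319, 455 and 14, with 18 in both, and at 0.01 they were 4, 75, 129, 4 and 1100, with 3 in both. With an estimated correlation 1, 0 and 1 lists were called in the null, transgenic and difference, where 3, 3 and 2 had an unadjusted p under 0.05. Fry called 0 and 1 lists in the null and transgenic (4 and 5 unadjusted), and the exact test 0 in the null (5 unadjusted). The null long-gene shift was 0.0342 over 200 kb (exact p = 0.0397), 0.0306 with genes matched on expression (exact p = 0.0238) and 0.0142 over 50 kb, where it did not pass (exact p = 0.429). Without the 4 arrays 3, 115, 139, 3 and 1023 genes were called, 2 in both, r was -0.166 and 3 lists were called for the difference. With the gene median as a covariate 18 genes were called in the null (12 higher and 6 lower) and 317 in the transgenic, r was -0.162, and 3 lists were called in the null and 3 for the difference. Without Cck the Purkinje list was not called in the transgenic (adjusted p = 0.0642). These counts in both comparisons are of genes with opposite signs. Stap2 was also called in both, with the same sign, with the run as a block, after quantile normalization, with centred arrays, above the median signal, with the mean of the probe sets, with array weights, at an adjusted p under 0.1 and without wild-type FVB replicate 2, and Pappa with the mean of the probe sets and without null replicate 2.

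With 1 array left out the counts ran from 5 to 64 in the null, 118 to 210 in the transgenic, 234 to 382 for the difference, 4 to 12 for the mean and 1506 to 2306 between strains. In both comparisons 3 to 16 genes were called, and r ran from -0.209 to -0.0799. The long-gene shift ran from 0.0127 to 0.0348 in the null and from -0.0374 to -0.0320 in the transgenic. The lists called ran from 4 to 6 in the null, 4 to 10 in the transgenic and 3 to 7 for the difference. The strain contrast could not be estimated under the blocks, nor the difference and mean in fits of single strains. The replicate block gave no long-gene test, since 5 pairs cannot reach p under 0.05 in an exact test. Robust priors and the remaining settings moved no count by over 1.5 times.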

Other observations

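The fits without the 4 arrays that stood apart and with the gene median as a covariate, and the choice of these lists for description, came only after the results were seen. Imprinted genes were the list whose difference between the genotypes held in the most settings: they lay lower in the transgenic relative to the null in all 34 settings tried, with camera and fry adjusted p from 2.15e-05 to 0.0241. The growth regulator Plagl1 changed by 0.30 log2 in the null and -0.40 in the transgenic, the noncoding Mirg by 0.29 and -0.41, and Nap1l5 by 0.12 and -0.33, of which the transgenic values passed the threshold. Grb10, named after its value was seen, went the other way in the transgenic, at 0.35 (adjusted p = 0.0481). The microglia list had the next most stable difference, called in 32 of 33 settings and lost with an estimated correlation (adjusted p = 0.169 with an estimated correlation).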
